A study of Xenopus laevis with 18 samples.

How the data were processed

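RNA from lateral marginal zone explants was measured on Affymetrix Xenopus laevis arrays, from biotin-labelled cRNA made from 6 µg of total RNA, in 6 groups (2 labelled arms at 3 stages) of 3 arrays, 18 in all, which the labels call biological replicates. The deposited values are log2 probe set intensities that the authors made by RMA with the affy package per the submitters' processing notes, with background correction, quantile normalization and median polish. The versions and the set of arrays normalized together are not stated. The deposited table held 32635 probe sets with values on every array. Array medians lay between 5.85 and 5.91 at early gastrula, 5.47 and 5.51 at mid-gastrula, and 5.48 and 5.51 at early neurula. Samples were grouped by the labels as they stand.

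The 160 Affymetrix control probe sets were left out, and 32475 were tested. Gene symbols came from the annotation paired with the probe sets: 15495 had 1 symbol, 279 had several and 16701 had none, giving 11303 genes. Of the probe sets with 1 symbol, 15384 had an Entrez gene identifier found in the reference gene table of the Xenopus_laevis_v10.1 assembly, from which names alone were taken. For the 2702 genes with several probe sets, the probe set with the highest mean over the arrays stood for the gene, and homeologs (.L and .S) were kept as separate genes.

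A linear model over all 18 arrays with a mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes). It gave the difference between the labelled arms at each stage, their mean over the stages, the differences between stages, and the time contrasts among explants labelled control. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast; SE is limma's moderated standard error and SD that of 3 arrays. Overlaps and shares were tested with Fisher's exact test on probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

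The replicate numbers were checked for pairing. After group means were removed, arrays of the same stage and number correlated across genes between the arms (r from 0.83 to 0.84 at early gastrula, 0.73 to 0.78 at mid-gastrula and 0.64 to 0.74 at early neurula). Arrays with other numbers gave r from -0.48 to -0.11, which the removal of the group means of 3 arrays makes negative. Genes are not independent replicates. Before that removal, same-numbered arrays of the arms of a stage correlated at 0.994 to 0.998, and arrays of the same group at 0.9874 to 0.9927. The median residual SD was 0.154 without and 0.123 with the number as a block. The fit without the block, which ignores the pairing, is the one reported first. Blocked calls are given beside it where those over all probe sets differ. The block took the replicate number alone, shared by all stages. Pairs within a stage were not fitted as blocks of their own, so neither fit takes up all of the pairing.

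Genes were named by a rule written before the data were examined. For each difference between the arms it took up to 10 genes per direction with the largest change among called genes whose arrays did not overlap between the arms, up to 4 called members of each list, and a panel of 24 genes given whatever their result. Of the panel 19 were measured, as 26 homeologs, and the others had no probe set with their symbol. For each time contrast it took 6 genes per direction and called list members. Named genes numbered 26 at early gastrula, 28 at mid-gastrula and 48 at early neurula. List members named because they passed over the list alone were chosen after their values were seen.

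In the same way 17 gene lists were written beforehand, from general knowledge: RA metabolism and receptors, literature RA-responsive genes, Hox paralogs 1 to 5, Hox paralogs 6 to 13, TALE homeobox cofactors, pronephric kidney field and tubule, cardiac and anterior lateral plate, blood and endothelium, paraxial mesoderm and muscle, early mesoderm and ventral or posterior signals, organizer and axial mesoderm, endoderm, neural tissue, neural crest, epidermis and ciliated cells, stress and cell death, and reference genes. Some genes stand in several lists. Each list was tested with limma's camera (preset correlation 0.01) on 1 probe set per gene, with p adjusted over 51 tests, and again with an estimated correlation, with fry, with the replicate block and with every probe set.

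Alternatives were the replicate number as a fixed or a random block, only the compared arrays, a filter on dim probe sets (log2 of at least 6 on at least 3 arrays, which kept 18223), repeated quantile normalization, median centring, a trended and robust variance, array weights, leaving out probe sets that can match several transcripts (2331), a 2-fold minimum, and leaving out each array. The fit was tested on simulated data for the early neurula comparison, with 32475 probe sets and 200 changed in each of 5 runs: without the block it recovered 42.1%, 83.6% and 95.5% of log2 changes of 0.5, 1 and 2, and with it 60%, 93.4% and 99.1%. Each simulated probe set had the same spread in every group and a replicate effect shared by the stages. The recovered shares therefore need not hold where the spread or the pairing differs by stage. With 11303 genes, camera called 100% of 20 simulated lists of 30 genes moved by 0.3 and 2% of 100 lists left in place. The simulated genes of this list test were independent. It therefore says nothing about false calls of lists whose genes move together, such as Hox paralogs 6 to 13 (estimated correlation 0.592) and 1 to 5 (0.445). With 3 arrays per group, an exact permutation test of 1 gene within 1 stage cannot reach 0.05, so no such test is given. None over the stages together was run. Scans were not analysed here.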

Results

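The series profiled lateral marginal zone explants of Xenopus laevis, the flank of the gastrula that gives rise to lateral mesoderm and to the field of the pronephros, the embryonic kidney. Embryos were injected at the 4-cell stage with GFP mRNA alone (labelled control) or with GFP and cyp26 mRNA (labelled RA-depleted), cyp26 being an enzyme that breaks down retinoic acid (RA). Explants were cut at early gastrula and cultured for 1 h (early gastrula) or 3 h (mid-gastrula) at 20 °C, or overnight at 14 °C (early neurula). Each of the 6 groups held 3 arrays described as biological replicates, 18 in all, and the labels do not say what a replicate number shared. The question put by the study's title is which genes of lateral mesoderm are targets of RA. Deposited log2 values ran from 2.49 to 14.59, and the median array value was 5.88 at early gastrula, 5.5 at mid-gastrula and 5.49 at early neurula. With 3 arrays per group, the number of arrays limits the precision of every difference.

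The cyp26a1 reading, checked before any other, ran against the labels on every array. The bright probe set of cyp26a1.S (Xl2.456.1.S1_at) stood at 13.79 ± 0.08 (SD, n = 3) in early gastrula explants labelled control and at 9 ± 0.46 in those labelled RA-depleted. At mid-gastrula the means were 13.76 ± 0.15 in the arrays labelled control and 8.42 ± 0.12 in those labelled RA-depleted, and at early neurula 13.26 ± 0.24 and 9.12 ± 0.49. The single arrays labelled control, in the order of their replicate numbers, read 13.88, 13.72 and 13.76 at early gastrula, 13.92, 13.65 and 13.70 at mid-gastrula, and 13.53, 13.05 and 13.21 at early neurula. Those labelled RA-depleted read 9.31, 9.21 and 8.48, then 8.56, 8.34 and 8.35, then 9.38, 9.44 and 8.55. The reading was lower in the array labelled RA-depleted in 9 of 9 same-numbered pairs, by a log2 difference between -3.61 and -5.37. The labels do not name the cyp26 gene or species that was injected, and the strand or region that each probe set covers was not analysed here. For this reason the arms are called by their labels throughout, every direction follows those labels, and each sign would turn if the arm labels were exchanged.

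**Figure D1:**
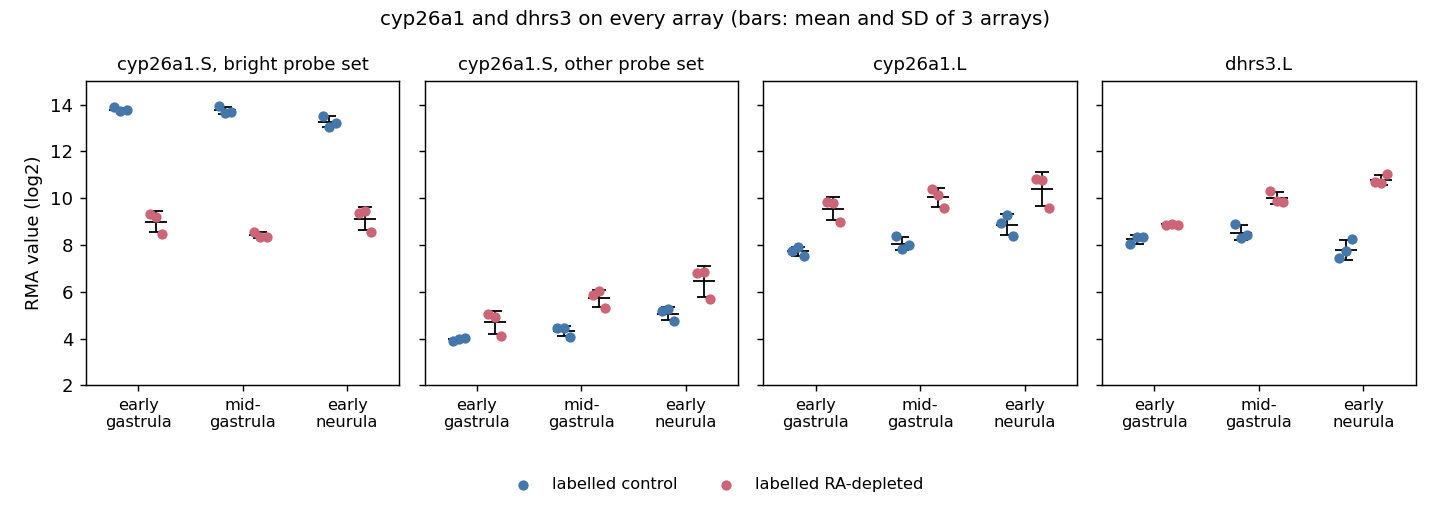
Deposited log2 values (vertical axis) of 2 cyp26a1.S probe sets, cyp26a1.L and dhrs3.L on each of the 18 arrays, by stage (horizontal axis) and labelled arm, with the mean and SD of 3 arrays. The bright cyp26a1.S probe set lies above 13 on the arrays labelled control and below 9.5 on those labelled RA-depleted, while the other 3 probe sets have higher means in the arm labelled RA-depleted.

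The homeolog of that gene and its other probe set read the opposite way. The homeolog cyp26a1.L was higher in the arrays labelled RA-depleted by a log2 difference of 1.82 (SE 0.34) at early gastrula, 1.99 (SE 0.34) at mid-gastrula and 1.53 (SE 0.34) at early neurula, in 9 of 9 pairs. None of these single-stage differences passed the test (adjusted p = 0.856, 0.148 and 0.0798), but all of them did with the replicate block (adjusted p = 0.00586, 0.00102 and 0.00135). The mean over the stages passed without it, at 1.78 (SE 0.20, adjusted p = 0.000762). The other probe set of cyp26a1.S (Xl2.50113.2.A1_a_at), which was dim, gave 0.72 (SE 0.30), 1.39 (SE 0.30) and 1.38 (SE 0.30) at the same stages, and a mean of 1.17 (SE 0.17, adjusted p = 0.0147). No single stage of it passed (adjusted p = 1, 0.890 and 0.0702), and with the block mid-gastrula and early neurula did (adjusted p = 0.923, 0.0139 and 0.00135). So the 2 probe sets of cyp26a1.S disagreed in sign at each stage.

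In early gastrula explants, 1 h into culture, cyp26a1.S was the single gene called between the labelled arms without the replicate block. It was 27.6-fold lower in the arrays labelled RA-depleted (log2 difference -4.79, SE 0.23, adjusted p = 7.36e-08, n = 3 per arm). The retinaldehyde reductase gene dhrs3.L, a known RA target, read 0.64 higher (SE 0.20, adjusted p = 1) and the zinc finger gene znf703.S 0.54 higher (SE 0.12, adjusted p = 1), neither past the test. The Hox gene hoxa3.S (-0.07, SE 0.15), the kidney regulator lhx1.L (0.11, SE 0.27) and the RA-synthesising enzyme aldh1a2.L (-0.20, SE 0.16) lay within 2 SE of 0. limma called 1 of 32475 probe sets, with 492 at an unadjusted p under 0.05. The 492 are a smaller share than the 0.05 that no difference at all would give. The test thus looks conservative here, and 1 call does not show that little differed. With the replicate block 2 were called, cyp26a1.L being the second.

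Of the gene lists at early gastrula, 26 measured endoderm genes had a median difference of -0.22 and 3 of the 26 lay above 0 (camera adjusted p = 2.24e-08, but adjusted p = 0.315 with an estimated correlation). No endoderm member passed over all probe sets, and adjusted over the list alone 1 was lower, a2m.S, which encodes a secreted protease inhibitor. List members that passed over the list alone are named after their values were seen, here and at the later stages. The block made 5 endoderm members lower adjusted over the list alone, and none over all probe sets. The 20 stress and cell death genes had a median of -0.16 and 1 of them lay above 0 (camera adjusted p = 2.06e-05; adjusted p = 0.121 with an estimated correlation), led by the immediate early genes atf3.L (-0.63, SE 0.33) and jun.L (-0.51, SE 0.23), which did not pass singly. Smaller shifts were called by camera for 28 cardiac and anterior lateral plate genes (median -0.04, adjusted p = 0.0222; adjusted p = 0.326 with an estimated correlation) and for 38 neural genes (median 0.04, adjusted p = 0.0111; adjusted p = 0.378 with an estimated correlation). The literature RA-responsive list had a median of 0.03, a mean of -0.08 and a camera direction upward that did not pass (adjusted p = 0.208). The count of its members past the test was 1 of 15, cyp26a1.S. Adjusted over the list alone, cyp26a1.L, dhrs3.L and znf703.S were higher as well.

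After 3 h of culture, at mid-gastrula, 3 named genes were higher in the arrays labelled RA-depleted and cyp26a1.S was lower. dhrs3.L was 2.76-fold higher (log2 1.47, SE 0.20, adjusted p = 0.0168), tdgf1.2.S, a member of the Cripto family of Nodal co-receptors, 1.93-fold (0.95, SE 0.13, adjusted p = 0.0168), and znf703.S 1.83-fold (0.87, SE 0.12, adjusted p = 0.0168), each in 3 of 3 pairs. cyp26a1.S was 40.5-fold lower (log2 -5.34, SE 0.23, adjusted p = 1.54e-08). The posterior homeobox cofactor meis3.L read 0.99 (SE 0.34), the pan-neural gene sox2.L 1.40 (SE 0.40), the myogenic gene myod1.L 0.85 (SE 0.41) and hoxb4.S 0.85 (SE 0.42), all with adjusted p = 1. Of the kidney field genes, pax8.L (-0.04, SE 0.14), osr1.L (-0.35, SE 0.25) and lhx1.L (0.35, SE 0.27) lay within 2 SE of 0.

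limma called 6 probe sets at mid-gastrula, 5 higher and 1 lower, 2 of the higher without a gene symbol, and 12 with the replicate block, 11 of them higher. The calls of dhrs3.L, znf703.S and tdgf1.2.S were each lost without any 1 of 5 of the 6 arrays, though their log2 differences stayed between 1.32 and 1.64, 0.78 and 0.98, and 0.84 and 1.06. The count was 3 without array 1 of those labelled RA-depleted, 2 without array 2, 3 without array 3, and 3 without array 3 of those labelled control.

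Among the lists at mid-gastrula, all 8 measured genes of Hox paralogs 1 to 5 lay above 0 (median 0.20, camera adjusted p = 0.000218; adjusted p = 0.326 with an estimated correlation), none past the test over all probe sets and 0 adjusted over the list alone (2 with the replicate block). Hox paralogs 6 to 13 had a median of 0.16 over 17 genes (adjusted p = 0.0120; adjusted p = 0.649 with an estimated correlation), with hoxc6.S at 1.26 (SE 0.42) and 1 gene higher over the list alone with the block. Paraxial mesoderm and muscle genes had a median of 0.18, 30 of 40 above 0 (adjusted p = 3.54e-05; adjusted p = 0.358 with an estimated correlation). Organizer and axial mesoderm genes had a median of 0.21, 20 of 28 above 0 (adjusted p = 0.00358; adjusted p = 0.421 with an estimated correlation), with the Nodal ligand nodal.L at 1.15 (SE 0.35). The literature RA-responsive genes had a median of 0.24 (adjusted p = 0.000562; adjusted p = 0.150 with an estimated correlation). Of these genes 2 were higher and 1 lower, and 4 and 1 adjusted over the list alone, meis3.L and cyp26a1.L being the additions. With the block cyp26a1.L passed over all probe sets as well, and 5 were higher over the list alone. Over the list alone the block called 2 early mesoderm genes higher, and 1 endoderm and 1 epidermis gene lower, where 0 passed without it. Endoderm genes again lay below 0 (median -0.21, 5 of 26 above 0, adjusted p = 1.24e-05; adjusted p = 0.356 with an estimated correlation), as did pronephric genes by a median of -0.06 (adjusted p = 0.0222; adjusted p = 0.358 with an estimated correlation and 0.116 with every probe set), nos1.L being lower adjusted over the list alone. The neural list was not called (median 0.00, adjusted p = 0.0556, and 0.00775 with every probe set), yet adjusted over the list alone sox2.L, gbx2.1.S, gbx2.2.L and the neuronal RNA-binding gene elavl3.L were higher.

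In early neurula explants more genes were called than at the earlier stages, most of them higher in the arrays labelled RA-depleted. Among genes with a symbol dhrs3.L was 7.91-fold higher (log2 2.98, SE 0.20, adjusted p = 2.42e-06), the semaphorin gene sema3fl.S 4.99-fold (2.32, SE 0.16, adjusted p = 2.42e-06), the collagenase gene mmp13.S 5.36-fold (2.42, SE 0.37, adjusted p = 0.00499) and the nuclear receptor gene nr5a2.S 4.15-fold (2.05, SE 0.25, adjusted p = 0.00105). lhx1.L, a LIM homeobox regulator of the kidney field, was 3.99-fold higher (2, SE 0.27, adjusted p = 0.00234), from 6.87 ± 0.77 (SD, n = 3) to 8.86 ± 0.33. Lower in the same arrays were cyp26a1.S (17.6-fold, log2 -4.14, SE 0.23, adjusted p = 2.96e-07), spam1.L, named for a sperm hyaluronidase (-2.34, SE 0.27, adjusted p = 0.000620), and the early mesodermal T-box gene eomes.L (-0.78, SE 0.15, adjusted p = 0.0373). The probe sets of nr5a2.S (mean 4.18 over all 18 arrays) and spam1.L (4.3) lay at the dim end. The sizes of their changes are read as lower limits for those probe sets, not for every probe set of the genes. As at the other stages, these directions follow labels that cyp26a1.S runs against.

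The largest higher values belonged to 3 probe sets without a symbol, chosen after their values were seen: Xl2.283.1.S1_at (4.11, SE 0.30), Xl2.23512.1.S1_at (3.45, SE 0.26) and Xl2.9073.1.A1_at (3.03, SE 0.13). Further genes with a symbol on the higher side were prph.L, a neuronal intermediate filament (1.99, SE 0.26), pgam2.L, a muscle phosphoglycerate mutase (1.98, SE 0.33), lrrn1.L, a leucine-rich repeat membrane protein (1.90, SE 0.26), col9a1.L, a collagen IX chain (1.86, SE 0.34), and the adenylate kinase gene ak1.L (1.64, SE 0.24). On the lower side pnhd.L, named after its values were seen, had a called probe set at -1.20 (SE 0.20, adjusted p = 0.0101), but the probe set that stands for it did not pass. By the naming rule followed dcbld1.S (-0.88, SE 0.14), the metalloproteinase inhibitor gene timp2.S (-0.84, SE 0.15), the crystallin gene cryba2.S (-0.78, SE 0.12), lrwd1.L (-0.72, SE 0.12), mob2.2.S (-0.71, SE 0.14), has-rs.S (-0.57, SE 0.12) and depdc7.L (-0.49, SE 0.10). Each of the 12 genes that the rule named here passed the test and moved the same way in 3 of 3 pairs. The other probe sets of nr5a2.S (0.08) and lrrn1.L (0.18) did not follow, of the other 2 for lhx1.L 1 read 1.21 and 1 read 0.01, and that of ak1.L read 1.80.

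limma called 138 probe sets at early neurula, 121 higher (59 genes with a symbol) and 17 lower (12 genes), and 370 with the replicate block, 263 higher and 107 lower, with all 138 among them. The count was 218 without array 3 of those labelled control, 41 of them lower. The number lower was 8 without array 1 and 31 without array 3 of those labelled RA-depleted. Fitted on its own 6 arrays alone the stage gave 6 calls, with fewer degrees of freedom and its own spread. Of the named calls cyp26a1.S, dhrs3.L and sema3fl.S passed there. The full fit shares 1 spread over all groups, which can lie under the neurula spread of a gene that is dim earlier. For hoxa3.S the SD was 0.37 (labelled RA-depleted) and 0.26 (labelled control) at neurula, against 0.05 and 0.11 at early gastrula. The SE and adjusted p of such genes may therefore be too small. Of the 26 named genes called, 12 lost the call without at least 1 array: timp2.S, eomes.L, lrwd1.L, mob2.2.S, has-rs.S, depdc7.L, znf703.S, hoxa3.S, ripply2.2.S, gbx2.1.S, col9a1.L and pgam2.L.

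**Figure D2:**
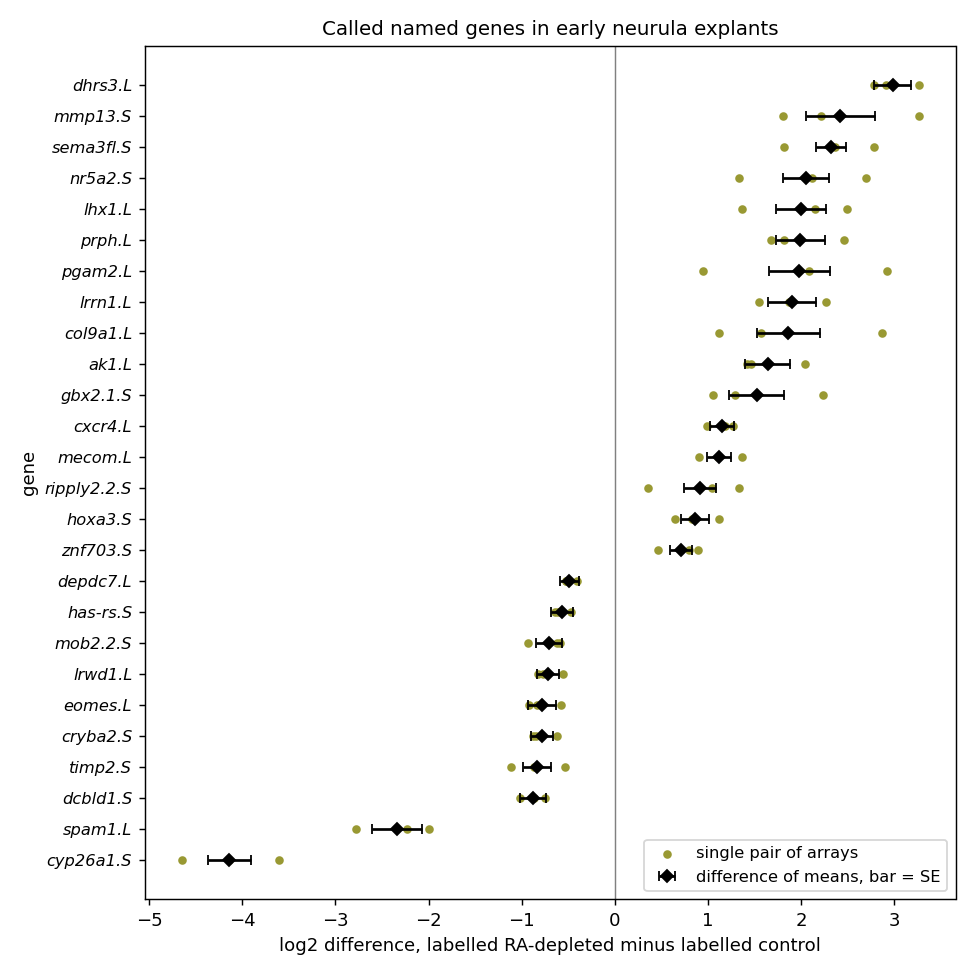
The 26 named genes called at early neurula, with the log2 difference between the labelled arms on the horizontal axis. Diamonds are differences of means with their SE and dots the 3 same-numbered pairs, from dhrs3.L at 2.98 to cyp26a1.S at -4.14; every pair of a gene lies on the same side of 0.

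Of the lists closest to RA, the literature RA-responsive genes and Hox paralogs 1 to 5 were called by camera at early neurula, and RA metabolism and receptors was not. Of 15 measured literature RA-responsive genes, 3 rose (dhrs3.L, znf703.S at 0.71 with SE 0.12, and hoxa3.S at 0.86 with SE 0.15) and cyp26a1.S fell by 4.14, with 11 not past the test. Adjusted over the list alone 7 were higher and 1 lower, with cyp26a1.L, meis3.S, meis3.L and the nuclear receptor gene nr2f2.L added. Under the block cyp26a1.L and meis3.L passed over all probe sets too, and over the list alone 2 were lower. The list median was 0.57 (camera adjusted p = 2.33e-05; adjusted p = 0.121 with an estimated correlation). Of 8 measured genes of Hox paralogs 1 to 5, which pattern the hindbrain and anterior trunk, hoxa3.S rose. Adjusted over the list alone 4 were higher, with hoxb2.S (1.22, SE 0.40), hoxc5.L (0.89, SE 0.23) and hoxa2.L (0.74, SE 0.19) added. With the block hoxa2.L and hoxc5.L also passed over all probe sets, and 5 over the list alone. The list median was 0.66 (adjusted p = 2.13e-07; adjusted p = 0.176 with an estimated correlation). Of Hox paralogs 6 to 13, of the more posterior trunk and tail, 0 of 17 passed, 0 adjusted over the list alone, and the median was -0.08 (adjusted p = 0.495). The difference between these Hox lists was not tested. hoxa3.S lost its call without array 1 of those labelled RA-depleted (0.66) and without array 3 of those labelled control (0.71), and znf703.S without array 2 of those labelled control (0.68).

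TALE homeobox cofactors, partners of Hox proteins, had a median of 0.21 over 9 genes (adjusted p = 0.0555, and 0.00617 with every probe set), none past the test over all probe sets, and meis3.L (1.55, SE 0.34, adjusted p = 0.0702, 0.0403 with the replicate block), meis3.S (1.01, SE 0.25) and meis2.L (0.50, SE 0.15) higher adjusted over the list alone. The RA metabolism and receptor list moved both ways, with dhrs3.L higher, cyp26a1.S lower and a median of 0.01 over 22 genes (adjusted p = 0.887). Adjusted over the list alone cyp26a1.L and the receptor gene rara.L (0.66, SE 0.17) were higher too, and with the block they passed over all probe sets and 3 were lower over the list alone, while aldh1a2.L read 0.10 (SE 0.16). A probe set of cyp26c1.S (Xl2.1946.1.A1_at), chosen after its values were seen, was higher by a log2 of 1.87 (SE 0.28, adjusted p = 0.00443). Its arrays labelled control read 4.05, 3.45 and 4.58, at the dim end, so the value is a lower limit for that probe set alone. The probe set that stands for the gene read 0.13 (SE 0.08).

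Of 29 pronephric genes, lhx1.L and the zinc finger gene mecom.L (1.12, SE 0.13, adjusted p = 0.000683) rose and the other 27 did not pass. The same 2 were called adjusted over the list alone (3 over all probe sets and 5 over the list alone with the block), and the median was 0.08 (adjusted p = 0.0217; adjusted p = 0.358 with an estimated correlation). osr2.L read 0.74 (SE 0.28, adjusted p = 0.591, 0.00312 with the replicate block) and osr1.L 0.69 (SE 0.25), whereas pax8.L (-0.05, SE 0.14) and pax2.L (0.02, SE 0.13) lay near 0. The probe set that stands for mecom.L was dim, with a mean of 3.87 over all arrays, so its rise is a lower limit for that probe set alone. Another mecom.L probe set, chosen after its values were seen, was also dim (mean 3.66). It was called by limma at 0.66 (SE 0.11, adjusted p = 0.0115).

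Paraxial mesoderm and muscle genes had at early neurula a median of 0.42, 30 of 40 above 0 (camera adjusted p = 2.13e-07; adjusted p = 0.326 with an estimated correlation), and the somite repressor gene ripply2.2.S rose (0.91, SE 0.17, adjusted p = 0.0236). Adjusted over the list alone 6 were higher: ripply2.2.S, ripply2.1.S (1.2, SE 0.30), the segmentation gene mespa.L (1.21, SE 0.28), tbx1.L (1.17, SE 0.36), the muscle filament gene des.1.L (1.00, SE 0.29) and myf6.S (0.59, SE 0.19). Blocked, mespa.L and ripply2.1.S passed over all probe sets as well, and 12 over the list alone. Early mesoderm and ventral or posterior signalling genes had a median of -0.31, 7 of 42 above 0 (adjusted p = 3.53e-10; adjusted p = 0.326 with an estimated correlation). eomes.L fell by 0.78, and adjusted over the list alone 4 were lower, with vegt.S (-1.08, SE 0.26), sp5.L (-1.13, SE 0.25) and bmp4.S (-0.55, SE 0.15). With the block vegt.S and sp5.L passed over all probe sets as well, and 7 were lower over the list alone. The notochord and early mesoderm gene tbxt.S read -0.55 (SE 0.21, adjusted p = 0.682). ripply2.2.S and eomes.L each lost the call without any 1 of 4 of the 6 arrays, with log2 differences between 0.73 and 1.11 and between -0.62 and -0.92.

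Blood and endothelium genes had a median of -0.06 over 29 genes, 0 past the test and 0 adjusted over the list alone (camera adjusted p = 0.0191; adjusted p = 0.356 with an estimated correlation), with tal1.S at -0.31 (SE 0.09, adjusted p = 0.260). Cardiac and anterior lateral plate genes had a median of 0.04 over 28 (adjusted p = 0.722), with the heart regulator nkx2-5.S at -0.79 (SE 0.52, adjusted p = 1). Of 26 endoderm genes the chemokine receptor gene cxcr4.L rose (1.15, SE 0.13, adjusted p = 0.000311) and the others did not pass, with a median of -0.04, a mean of 0.05 and no call (adjusted p = 0.984). The block added calls of cxcr4.S, foxa1.L and darmin.L, and over the list alone 6 were higher and 2 lower. cxcr4.L is also active outside endoderm. Of 38 neural genes gbx2.1.S, a homeobox gene of the posterior neural plate, rose (1.52, SE 0.30, adjusted p = 0.0420), and adjusted over the list alone 5 were higher and zic2.L lower (-0.49, SE 0.12), around a median of 0.01 (adjusted p = 0.578). With the block sox11.S passed over all probe sets as well, and 2 were lower over the list alone.

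Neural crest (median 0.01 over 21 genes, adjusted p = 0.722), organizer and axial mesoderm (-0.03 over 28, adjusted p = 0.696), epidermis and ciliated cells (-0.02 over 34, adjusted p = 0.722), stress and cell death (-0.01 over 20, adjusted p = 0.898) and reference genes (0.03 over 16, adjusted p = 0.441) were not called at early neurula, and 0 members of any of them passed, over all probe sets or adjusted over the list alone, without the block. With the block foxa1.L of the epidermis list passed over all probe sets, and over the list alone 2 epidermis genes were higher and 1 lower, 1 organizer gene was higher and 1 lower, and 1 stress gene was lower. The means of the organizer (0.02), epidermis (0.09) and stress (0.04) lists had the other sign from their medians. Reference gene odc1.L read 0.03 (SE 0.09). Over the 17 lists and 3 stages camera called 17 of 51 tests, and 0 of 51 held with an estimated correlation. That correlation was estimated without the block, so it may include variation shared by same-numbered arrays.

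**Figure D3:**
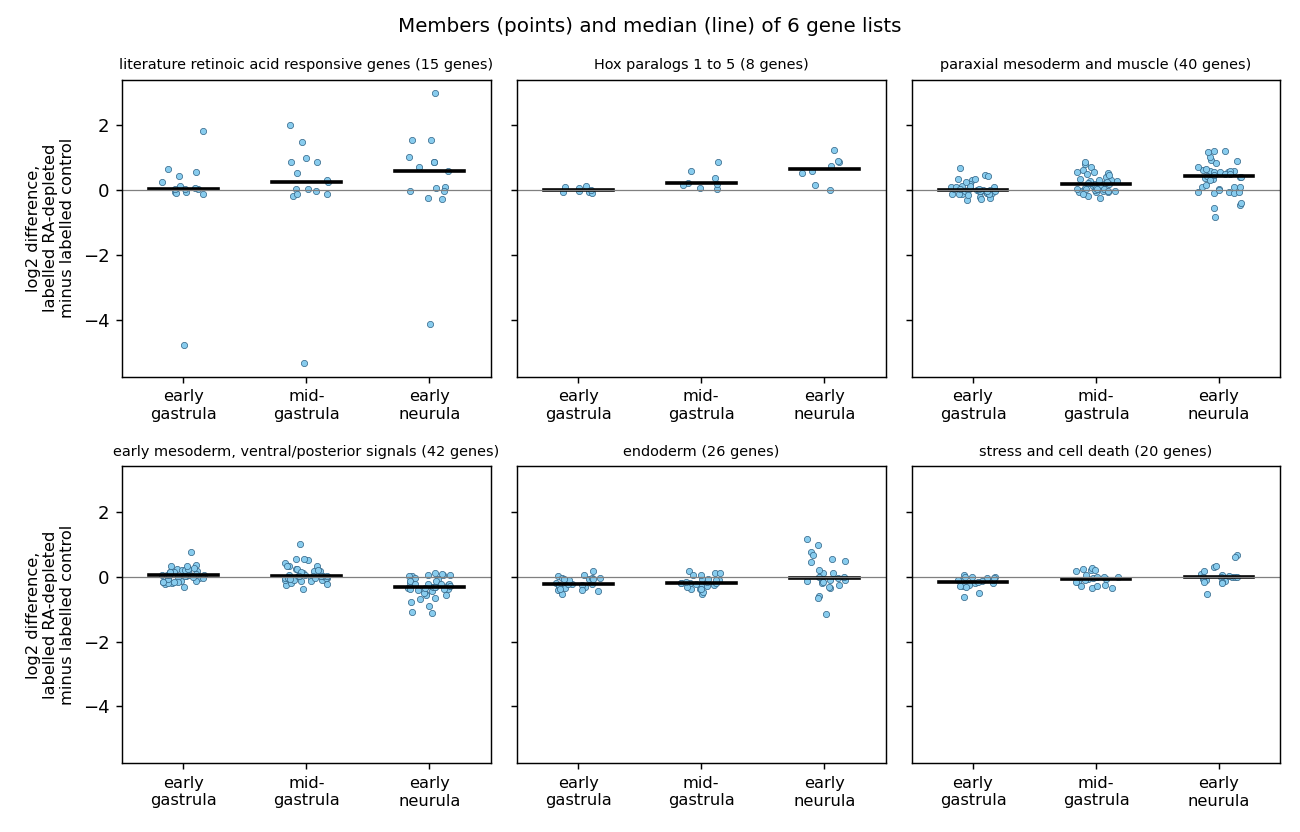
Log2 differences between the labelled arms (vertical axis) of the members of 6 lists at the 3 stages (horizontal axis), with the list median as a line. The median of Hox paralogs 1 to 5 goes from -0.01 to 0.20 to 0.66 and that of early mesoderm and ventral or posterior signals from 0.04 to 0.01 to -0.31; the low point of the first panel is cyp26a1.S. The sign of the -0.01 turns with quantile normalization.

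Averaged over the stages, dhrs3.L (log2 1.70, SE 0.12, adjusted p = 4.58e-06), cyp26a1.L (1.78, SE 0.20), prph.L (1.26, SE 0.15), lrrn1.L (0.89, SE 0.15), sema3fl.S (0.74, SE 0.09), znf703.S (0.71, SE 0.07) and tdgf1.2.S (0.66, SE 0.08) were higher in the arrays labelled RA-depleted. cyp26a1.S was 27.0-fold lower (-4.76, SE 0.13, adjusted p = 2.84e-11). limma called 28 probe sets, 26 higher and 2 lower, and 171 with the replicate block, 97 higher and 74 lower. Without single arrays the count ran from 16 to 51: it was 17, 16 and 18 without arrays 1, 2 and 3 of early gastrula labelled control, 17 without array 1 of early gastrula labelled RA-depleted, 18 without array 3 of mid-gastrula labelled RA-depleted, and 51 and 45 without array 3 of early neurula labelled RA-depleted and control.

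The difference between stages was tested directly. From early gastrula to early neurula the difference between the arms grew for dhrs3.L by 2.35 (SE 0.29, adjusted p = 0.00281), sema3fl.S by 2.33 (SE 0.22, adjusted p = 0.000472), mecom.L by 1.22 (SE 0.19, adjusted p = 0.0205), tdgf1.2.S by 1.21 (SE 0.18, adjusted p = 0.0194) and cxcr4.L by 1.19 (SE 0.18, adjusted p = 0.0157), and that of spam1.L changed by -2.43 (SE 0.39, adjusted p = 0.0270). Of these genes dhrs3.L and cxcr4.L alone had log2 values of at least 6 in both arms at early gastrula. For the others a low signal at early gastrula and a later effect cannot be told apart. From mid-gastrula to early neurula sema3fl.S gained 2.41 (SE 0.22, adjusted p = 0.000314) and mecom.L 1.22 (SE 0.19, adjusted p = 0.0284), and spam1.L changed by -2.33 (SE 0.39, adjusted p = 0.0445). The test called 24 probe sets for neurula against early gastrula (23 higher, 1 lower; 62 with the replicate block) and 19 for neurula against mid-gastrula (18 higher, 1 lower; 53 with the replicate block). Between early and mid-gastrula limma called 0, with 394 at an unadjusted p under 0.05, and 0 with the replicate block. The 394 are also a smaller share of the probe sets than 0.05, so 0 calls do not show that the effects were alike. Without single arrays the first count ran from 11 to 51: 14 and 14 without arrays 1 and 2 of early gastrula labelled RA-depleted, 11 and 14 without arrays 1 and 3 of early gastrula labelled control, 38 without array 2 of early neurula labelled RA-depleted and 51 without array 3 of early neurula labelled control. The other ran from 7 to 35: 12, 7 and 10 without arrays 1, 2 and 3 of mid-gastrula labelled RA-depleted, 10, 9 and 7 without those labelled control, 35 without array 2 of early neurula labelled RA-depleted and 30 without array 3 of early neurula labelled control.

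The genes called at mid-gastrula stayed called at early neurula in the same direction. All 5 higher probe sets, among them dhrs3.L, znf703.S and tdgf1.2.S, were among the 121 higher at neurula (one-sided Fisher's exact test, p = 6.61e-13, against 0.0186 expected by chance), and cyp26a1.S was lower at all stages. With the replicate block 11 of 11 higher probe sets were shared, cyp26a1.L among them. Probe sets are not independent, so the p describes the overlap only; the stages share no arrays.

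In explants labelled control, actc1.L and ripply2.2.S were among the genes that rose most from early to mid-gastrula, and lefty.L and bix1.2.S among those that fell most. Relative to the array medians, muscle actin actc1.L rose by a log2 of 5.61 (5.22 as deposited, SE 0.24), ripply2.2.S by 4.91 (4.52, SE 0.17), the somite gene meox2.S by 4.48 (4.09, SE 0.27) and the lateral plate gene foxf1.L by 4.42 (4.03, SE 0.55). The Nodal antagonist lefty.L changed by -4.09 (-4.48, SE 0.29), the Nodal ligand nodal2.L by -3.23 (-3.61, SE 0.26) and the mix-type homeobox gene bix1.2.S by -4.02 (-4.40, SE 0.23). Of 40 paraxial genes 14 rose and 3 fell as deposited, and 20 rose and 0 fell after centring. Of 26 endoderm genes 5 rose and 14 fell, and 8 and 10 after centring. Of 15 literature RA-responsive genes 7 rose and 0 fell, and 10 and 0 after centring, with meis3.L at 2.94 (2.55, SE 0.34) and hoxb4.S at 2.57 (2.18, SE 0.42). The RA-binding protein gene crabp2.L rose by 4.05 (3.67, SE 0.30), while 5 of the 22 RA metabolism and receptor genes rose and 6 fell (12 and 3 after centring). All gene values named here passed the test. Rises from readings at the dim end of the arrays, such as 3.84 for actc1.L and 3.58 for ripply2.2.S at early gastrula, are read as lower limits, since no detection calls were used.

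limma called 16060 probe sets between these stages, 22.7% of them rising. The medians of the arrays labelled control changed by -0.389 between the stages, so the split depends on the scaling: 46.0% rose after quantile normalization and 70.0% after centring each array on its median. The medians of the RA metabolism, pronephric, cardiac, blood, organizer, neural and epidermis lists turned sign with the scaling, and none of them is given a direction here for this step.

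From mid-gastrula to early neurula, 25 of 40 paraxial mesoderm and muscle genes rose and 6 fell in explants labelled control, as deposited and after centring or quantile normalization. The myosin genes myh4.L (log2 8.62, SE 0.30) and mylpf.L (8.59, SE 0.28) and the collagen II gene col2a1.L (5.98, SE 0.23) rose, as did hoxa7.L (5.98, SE 0.42), hoxb9 (5.66, SE 0.33), hoxa3.S (4.29, SE 0.15) and the kidney gene pax2.L (4.48, SE 0.13). Their mid-gastrula means lay between 3.14 (col2a1.L) and 4.25 (hoxa7.L), at the dim end of the arrays, so the rises are read as lower limits. Of the Hox lists 7 of 8 genes of paralogs 1 to 5 rose and 17 of 17 of paralogs 6 to 13 (16 of 17 after quantile normalization), with 0 falling. The T-box gene eomes.S changed by -5.35 (SE 0.17), the head inducer cer1.S by -5.06 (SE 0.19), the endoderm regulator mixer.S by -4.90 (SE 0.18) and the early kidney gene osr1.L by -3.49 (SE 0.25). limma called 19252 probe sets, 56.0% rising (48.6% after quantile normalization), and array medians were alike at these stages.

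Across the whole interval, early gastrula to early neurula, actc1.L rose by 10.06 relative to the array medians (9.66 as deposited, SE 0.24), myl1.L by 9.44 (9.04, SE 0.50) and hoxc6.S by 7.06 (6.67, SE 0.42). mix1.S changed by -7.21 (-7.61, SE 0.17), mixer.S by -7.27 (-7.66, SE 0.18), eomes.S by -6.59 (-6.98, SE 0.17) and the mitotic cyclin gene ccnb1.S by -5.78 (-6.18, SE 0.20). The dimmer stage lay at a mean of 3 for myl1.L, 3.42 for hoxc6.S, 3.99 for eomes.S and 4.06 for mix1.S and ccnb1.S, so these changes are lower limits as well. Of 28 organizer and axial mesoderm genes 18 fell and 4 rose, with a median of -1.62 (-1.23 after centring), and of 40 paraxial genes 27 rose and 5 fell, with a median of 1.79 (2.19 after centring). lhx1.L, higher in the neurula arrays labelled RA-depleted, changed by -3.44 (-3.84, SE 0.27) over this interval, and cxcr4.L by -3.02 (-3.41, SE 0.13). limma called 22260 probe sets, 41.5% rising (48.2% after quantile normalization, 64.8% after centring). Stage is mixed with time in culture and, for the neurula, with culture temperature.

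Whether the genes that differ between the arms are those that normally change with time was tested with time contrasts that share no array with the effect. Of the 121 probe sets higher at early neurula, 19.0% fell between early and mid-gastrula in explants labelled control, against 38.3% of all others (two-sided Fisher's exact test, p = 7.94e-06). With the time contrast centred on the array medians, an alternative chosen after the data were seen, the shares were 14.0% and 16.7% (exact test, p = 0.541). The shares rising were 19.0% and 11.2% as deposited (exact test, p = 0.0131) and 47.1% and 38.9% centred (exact test, p = 0.0756). Of the 17 lower at neurula, 23.5% fell against 38.2% (exact test, p = 0.318) and 17.6% rose against 11.2% (exact test, p = 0.429). This changed when the replicate block was fitted. Of 107 lower probe sets 30.8% then fell against 45.4% (exact test, p = 0.00249) and 32.7% rose against 14% (exact test, p = 7.91e-07). Of 263 higher, 28.5% fell against 45.5% (exact test, p = 2.38e-08) and 22.8% rose against 13.9% (exact test, p = 0.000111). Both directions held fewer falling and more rising probe sets than the others. At mid-gastrula 80.0% of the 5 higher probe sets rose from early gastrula to early neurula against 28.4% (exact test, p = 0.0252), and 51.1% of the others after centring (exact test, p = 0.376). None of the 5 fell, against 40.1% (exact test, p = 0.0873). Of 11 higher with the block, 81.8% rose against 31% (exact test, p = 0.000752) and 9.1% fell against 43.3% (exact test, p = 0.0293). The block was not combined with centring, so these shares carry the shift of the array medians between early gastrula and the later stages.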

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

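The tests of exchanged arm labels, of a fall of endogenous cyp26a1, of the spread between replicates, of a scale factor per stage and of blocked splits for the differences between stages were chosen after the result was seen; the others were chosen before the data were examined.

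Of 49 named genes, 6 had a difference between the labelled arms that itself differed between stages, in 9 results, by limma's test of the difference. For early neurula against early gastrula these were dhrs3.L, the retinaldehyde reductase gene (2.35, SE 0.29; arm differences 0.64 and 2.98), sema3fl.S, a semaphorin gene (2.33, SE 0.22; -0.01 and 2.32), mecom.L, a pronephric zinc finger gene (1.22, SE 0.19; -0.09 and 1.12), tdgf1.2.S, a Nodal co-receptor gene (1.21, SE 0.18; -0.09 and 1.12), cxcr4.L, a chemokine receptor gene (1.19, SE 0.18; -0.05 and 1.15), and spam1.L (-2.43, SE 0.39; 0.09 and -2.34). For early neurula against mid-gastrula they were sema3fl.S (2.41, SE 0.22), mecom.L (1.22, SE 0.19) and spam1.L (-2.33, SE 0.39). With the replicate block all 9 passed as well. No test of a single array far from its group was run.

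The bright cyp26a1.S probe set was lower, and the RA-induced genes dhrs3.L and cyp26a1.L higher, in the array labelled RA-depleted in 9 of 9 pairs, which an exchange of the arm labels in all 9 pairs predicts for an injected cyp26 mRNA. That endogenous cyp26a1 falls under correct labels predicts a lower cyp26a1.L, which was instead higher by 1.78 (SE 0.20) over the stages. This cannot decide the question, because the cyp26a1.L probe set might read an injected cyp26 mRNA of unknown sequence. A fault of the cyp26a1.S probe set alone is argued against by the literature RA-responsive genes without cyp26a1 (13 genes, median 0.57 at early neurula, unadjusted p = 0.000116 with an estimated correlation). An exchange of labels, in the deposit or before it, is therefore a candidate explanation and a hypothesis only, since it was found and tested on the same arrays. Open is the injected sequence, which the labels do not give. Biological feedback that raises RA-induced genes under cyp26 was not tested, and alone it would not lower the bright cyp26a1.S reading. That reading lay between percentiles 99.51 and 99.98 of the arrays labelled control, and between 78.91 and 88.93 of those labelled RA-depleted. For this probe set the values argue against such feedback as the whole cause.

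More probe sets were called at early neurula (138) than at early gastrula (1). A smaller spread at neurula is argued against by the ratio of the median SD within groups, which was 1 over all probe sets. Genes dim at early gastrula, such as hoxa3.S, spread more at neurula, and the shared spread may make their SE too small. Of the 24 probe sets whose arm difference differed between these stages, 16.7% had log2 values of at least 6 in both arms at early gastrula (4 of 24, among them dhrs3.L, cxcr4.L and vcan.L, the last chosen after its values were seen), and for the other 20 a low signal at early gastrula and a later effect cannot be told apart, because they lay under that level in at least 1 arm and no dilution shows what could be seen there. As many calls for this difference came from 7 of 100 splits of the arrays (24 real, 35 the highest other), so chance is not excluded for the count. A split can leave the neurula arms as they were, so this share cannot decide on chance. A later effect of the injection with stage remains an open biological explanation, and stage is mixed with time in culture and temperature.

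Array medians were lower at mid-gastrula than at early gastrula by a log2 change of -0.389 in explants labelled control. A scale factor from separate normalization of the stages would move hybridization spikes alike, and these changed by -0.017 (SE 0.084), which argues against a single factor as the whole cause. A change in the mix of transcripts with stage, or a normalization that acts differently along the intensity range, may be behind it and was not tested.

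For the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. As many calls as the real split came from 1 of 10 splits, the real 1, in each of them: at early gastrula (1 call, highest other 0), mid-gastrula (6, highest other 0), early neurula (138, highest other 18), and in the time contrasts from early to mid-gastrula (16060, highest other 0), mid-gastrula to neurula (19252, highest other 0) and early gastrula to neurula (22260, highest other 0). With the replicate block and splits that part every pair, 1 of 4 gave as many at mid-gastrula (12, highest other 0) and at early neurula (370, highest other 0), again too few splits for such a share. For the mean over stages, 2 of 100 splits gave as many calls as the real 28, and the other of these gave 1180. That split set both arrays numbered 1 against both numbered 3 at each of the 3 stages, which points to a structure of the arrays by replicate number. Because these splits ignore the replicate numbers, their share does not exclude chance. With the block and splits that part every pair, 1 of 100 gave as many as the real 171 (highest other 63), which argues against chance for the blocked count. Chance is not excluded for neurula minus mid-gastrula, with 9 of 100 (19 real, 63 the highest other). For mid-gastrula minus early gastrula any split matches the real count of 0 (0 by limma, 394 at an unadjusted p under 0.05; 100 of 100 splits, highest other 15), so the splits decide nothing there. These splits mix same-numbered arrays, so the 32 splits that part every pair were run with the block. As many calls came from 5 of 32 for neurula minus mid-gastrula (53 real, highest other 223) and 5 of 32 for neurula minus early gastrula (62 real, highest other 119). The highest other in each was the split that exchanges the arms of 1 whole stage, which turns the difference into a sum of effects. Without it the highest were 57 and 71, so chance is not excluded there either. Other splits exchange gastrula pairs alone and keep the neurula arms, where most calls lay. The splits of these differences, with or without the block, therefore cannot decide on chance. For mid minus early gastrula the real count with the block was 0 by limma (784 at an unadjusted p under 0.05), which 32 of 32 splits match of necessity (highest other 13). Like the 394 without the block, the 784 are a smaller share of the probe sets than 0.05.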

How the results depend on the processing

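Centring the time contrast on the array medians and leaving out a pair of arrays under the replicate block were chosen after the data were seen; the other alternatives were fixed before the data were examined.

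Where no value is given, counts stayed within 1.5-fold of the reported ones under quantile normalization, median centring, trended variance, array weights, the dim filter, the 2-fold minimum, single-transcript probe sets and the blocks. With the replicate number as a fixed block, calls were 2 at early gastrula, 12 at mid-gastrula, 370 at early neurula, 171 for the mean of stages, and 53 and 62 for neurula minus mid-gastrula and minus early gastrula. With a random block they were 3 at early gastrula, 323 at neurula, 106 for the mean, and 46 and 58. With only the compared arrays, which leaves fewer degrees of freedom and takes the spread from those groups alone, calls were 3 at mid-gastrula and 6 at neurula. They were 1, 4 and 7 for the differences mid minus early gastrula, neurula minus mid-gastrula and neurula minus early gastrula. The mean of stages uses every array and gave no such value. Array weights gave 46 for the mean. The 2-fold minimum gave 79 at neurula, 10 for the mean, and 4390, 6814 and 11285 for the time contrasts in the order of the stages. The dim filter, with fewer probe sets tested, gave 8 for neurula minus mid-gastrula, 10613 for mid against early gastrula and 14803 for neurula against early gastrula. Leaving out pair 2 under the block gave 3 at mid-gastrula. The causes of these changes in count were not tested.

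Leaving out single arrays gave 1 to 2 calls at early gastrula (2 without array 3 of those labelled RA-depleted), 2 to 5 at mid-gastrula, 99 to 218 at early neurula, 16 to 51 for the mean, 0 to 0, 7 to 35 and 11 to 51 for the differences between stages, and 14271 to 14757, 17559 to 18181 and 21133 to 21304 for the time contrasts; fewer arrays lower the degrees of freedom. Of the list calls, 0 held with an estimated correlation and 0 with fry, both run without the block. The replicate block with the preset correlation changed none. With every probe set of the listed genes 21 were called: TALE cofactors at neurula, neural, cardiac and early mesoderm genes at mid-gastrula and reference genes at early gastrula were added, and pronephric genes at mid-gastrula lost. Shared calls with the block were 2 for early and mid-gastrula, 12 for mid-gastrula and neurula and 2 for early gastrula and neurula. The share of higher neurula probe sets that fell with time was 14% after centring.

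The sign of cyp26a1.S turned with its other probe set, which gave 0.72, 1.39 and 1.38 at the successive stages; the cause was not tested. Under the other settings, called named genes kept direction and call in 216 results and lost the call in 29, and genes not called gained a call in 13. At neurula has-rs.S and depdc7.L lost the call with quantile normalization, and has-rs.S with array weights as well. Low signal limits the genes near the floor, where a change cannot be seen.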

Other observations

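The alternatives without a pair of arrays were chosen after the result was seen, and the genes in the next paragraphs were chosen after their values were seen.

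Some dim epidermis markers varied between single arrays, among them the keratin gene krt12.4.L. At early neurula the bright keratin gene krt8.1.S was alike in the arms: it read 13.39, 13.23 and 13.54 in the arrays labelled control and 13.36, 13.29 and 13.57 in those labelled RA-depleted. krt12.4.L read 7.40 in array 2 of mid-gastrula labelled RA-depleted, against 3.45 and 4.24 in the other arrays of that group and 3.52, 4.10 and 4.48 in those labelled control. At early neurula krt12.4.L read 3.15, 6.65 and 4.78 in the arrays labelled control and 6.59, 6.53 and 6.83 in those labelled RA-depleted. The markers itln1.L and krt70.L were higher in the array labelled RA-depleted in pair 1 alone of that stage: itln1.L read 8.70, 6.55 and 6.02 against 4.05, 7.12 and 6.18 in those labelled control, and krt70.L 8.32, 7.52 and 6.64 against 4.35, 8.10 and 7.93. In array 2 of mid-gastrula labelled RA-depleted krt70.L read 5.59 and krt12.5.S 6.50, against 3.33 and 2.84 in array 2 labelled control. At early neurula krt12.5.S read 3.32, 7.42 and 3.66 in the arrays labelled control and 6.50, 4.64 and 3.72 in those labelled RA-depleted, so pair 2 went the other way to pair 1. With the replicate block, 3 probe sets were called at mid-gastrula without pair 2, against 12 with all arrays. At early neurula 189 were called without pair 1, against 370 with all arrays. No other pair was left out for comparison, and fewer arrays lower the degrees of freedom. The lower counts therefore cannot be traced to these pairs.

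At early neurula the receptor gene fgfr3.L was 3.09-fold higher in the arrays labelled RA-depleted (1.63, SE 0.15, adjusted p = 7.64e-05 by limma) and the secreted Wnt modulator gene sfrp2.S 2.33-fold (1.22, SE 0.19, adjusted p = 0.00524). A probe set of hapln3.S, a gene of the hyaluronan matrix, read 2.58 (SE 0.27) and another 1.24 (SE 0.10, adjusted p = 1.22e-05), while the probe set that stands for the gene read 0.60 (SE 0.12). The first and second were dim (means of 4.02 and 4 over all arrays), so their differences are read as lower limits for those probe sets, not for the gene.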
